A study of Mus musculus with 6 samples.

How the data were processed

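RNA-seq of whole hearts from mice aged 4 days was compared between 3 Wtapflox/flox (Wtap-flox) and 3 Wtap-CKO libraries, grouped as the labels give them. The submitters selected polyadenylated RNA with poly-T beads and read 150 bases from each end on an Illumina instrument. Per the submitters' processing notes, reads were handled with CASAVA, aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, and the authors tested counts with DESeq2 1.20.0. The sources used here do not state the Cre driver, the deleted exons, the strandedness of the libraries or the thresholds of that test.

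The authors deposited FPKM values for 54532 genes, 22046 of them protein coding, with 1 column per library. FPKM times gene length was a whole multiple of a single step per library for 100.0% of values, within a tolerance of 0.01 of a step, so the counts per gene could be recovered. They are called reads here, but the values do not tell whether a unit is a single read or a read pair. The library sizes implied by the deposited values equalled median-ratio size factors, so the 6 columns had been scaled together. Reads recovered were 16589331, 15649028 and 17115796 in Wtap-flox 1 to 3 and 16485304, 15812407 and 18045599 in Wtap-CKO 1 to 3. The notes name GRCm39, but 94.7% of 20822 protein coding genes started or ended within 1000 bases of their place in GRCm38.p6, against 3.28% of 21689 in GRCm39. Coordinates are therefore given as GRCm38. How reads of overlapping genes were counted is not stated, and overlaps with coding genes are stated for genes where they matter, such as Acta1, Cdt1 and Slc7a5 with Gm20388, Myh7 with Gm17428, Mef2a with Lysmd4 and Mettl3 with Tox4. No per-sample column was left unused.

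Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, by a linear model on log2(FPKM + 1) with a variance trend and robust moderation. P values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The pseudocount of 1 understates fold changes of genes near that level. Each fold change is Wtap-CKO over Wtap-flox. Intervals are at 95%. Single measures were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

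A set of 41 gene lists with 866 symbols was fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives other than those given as added. In the file 854 symbols were found as written and 3 under an older symbol, and 9 were not found. In the file 100 symbols stood on more than 1 gene ID. Lists with at least 3 tested members were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry, all in limma. List calls under the alternatives are by camera at a correlation of 0.01 unless another test is named. Transcription factor families with at least 5 tested genes, as the file names them, were tested with camera.

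The text names Wtap and other m6A genes, a set of heart genes (Mef2a, Mef2c, Gata4, Nkx2-5, Tbx5, Myh6, Myh7, Nppa, Nppb, Ryr2, Atp2a2), and the 15 protein coding genes with the largest rise and the 15 with the largest fall. These had a mean of at least 5 FPKM, passed the threshold and did not overlap between groups, leaving out predicted and mitochondrially encoded genes. From each list it names up to 4 members with the smallest adjusted p and the first member in the opposite direction. It also allowed the 5 genes with the highest mean in each group. Not all genes the rule allows are printed.

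The procedure was tested on simulated data with 12619 tested genes. It recovered 74.7% of 99 genes changed 2-fold and 97% of 100 genes changed 4-fold, with 7 false among 178 calls (3.93%). A raised list of 30 genes was called and 0 of 40 unchanged lists were. All simulated genes shared a common dispersion of 0.0293, no library was set apart, and 200 genes were changed, evenly up and down. The share of false calls is therefore not an estimate for the gene calls in the real data. Simulated genes also varied independently of each other. In the real data the estimated correlation was 0.935 for monocyte and neutrophil markers and 0.829 for G2/M genes. The simulation therefore does not show how often camera calls unchanged lists whose genes are correlated.

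Alternatives were pseudocounts of 0.1 and 0.5, no filter and means of at least 0.1 and 5 FPKM, median-ratio, upper-quartile, quantile and TPM scaling, scaling without mitochondrially encoded genes, limma without the trend or without robust moderation, array weights, a replicate block, each library left out in turn, a log2 fold change of at least 1 and an adjusted p under 0.01. Limma-voom on recovered reads and a correction for GC content and gene length were added after the data were seen. Median-ratio scaling equals that of the deposited values and is left out of the tally of named genes. Ranges given over the alternatives leave out the replicate block. m6A levels were not analysed here.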

Results

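Polyadenylated RNA was sequenced from whole hearts of mice aged 4 days. The comparison was between 3 hearts of Wtapflox/flox mice, called Wtap-flox here, and 3 hearts labelled Wtap-CKO, the conditional knockout of the same gene. WTAP is a regulatory subunit of the enzyme complex that writes N6-methyladenosine (m6A) on messenger RNA. The submitters described the 3 hearts of each group as independent biological replicates, and the series is about the effect of WTAP on heart development. Between 15649028 and 18045599 reads or read pairs per library were assigned to genes. For a gene of 1 kb a single read or pair was worth between 0.0564 and 0.0647 FPKM, a count scaled by gene length and library size. All 6 libraries correlated more closely with their own group than with the other. The first principal component held 52.6% of the variance and separated the groups. The second held 20.4% and set Wtap-CKO 3 apart from the other Wtap-CKO libraries.

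The targeted gene itself was not lower in the hearts labelled Wtap-CKO. Wtap (ENSMUSG00000060475, chromosome 17, 12966796 to 12994169 on the minus strand, coordinates as in the file, which match GRCm38) stood at 7.77, 8.74 and 10.9 FPKM in the Wtap-flox libraries. In Wtap-CKO it stood at 9.32, 7.75 and 9.46 FPKM. The log2 fold change was -0.04 with a 95% interval of -0.37 to 0.29 (adjusted p = 0.893, limma), and the sign turned under some settings. An exact two-sided permutation test of the FPKM values gave p = 0.9, where 0.1 is the smallest p that 3 against 3 allows. The interval excludes a fall of the whole-gene value by more than 22.4% of FPKM + 1, which is 24.8% of FPKM. The values count reads over the whole gene, and the deleted exons are not given in the sources used here, so they do not check the labels. The groups below are therefore those of the labels, and every direction rests on them.

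Some other m6A genes differed in the libraries labelled Wtap-CKO. Rbm15, a subunit of the writer complex that binds RNA, rose from 3.20 ± 0.385 to 6.77 ± 1.53 FPKM (SD, n = 3; log2 fold change 0.87, adjusted p = 0.0081). It was the only 1 of the 8 measured members of the writer complex that passed, both over all genes and adjusted over the list alone (higher and lower: 0 to 1 and 0 to 1 over the alternatives). The catalytic subunits Mettl3 and Mettl14 had log2 fold changes of -0.22 (adjusted p = 0.215) and -0.33 (adjusted p = 0.0763), and the ubiquitin ligase homologue Cbll1 had -0.15. The list as a whole was not called (adjusted p = 0.577, camera), and its median of -0.05 and its mean of 0.00 differed in sign. Among 12 readers and erasers of m6A, 4 rose and 0 fell (3 to 4 and 0 over the alternatives), and 4 rose when adjusted over the list alone. They were the readers Igf2bp2 (0.87), Ythdf2 (0.80), Ythdf1 (0.64) and Ythdc1 (0.50). Ythdf1 missed the threshold without Wtap-CKO 1 (adjusted p = 0.0531) and Ythdc1 without Wtap-flox 2 (adjusted p = 0.063). Ythdc2 had -0.29, and the demethylases Fto and Alkbh5 had -0.16 and 0.18, none of which passed. As a list they were not called (adjusted p = 0.0881). They were called without Wtap-CKO 3 (adjusted p = 0.0353), without a filter, at a mean of at least 0.1 FPKM, with the GC and length correction and by fry (adjusted p between 0.0145 and 0.0448).

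Across the transcriptome, 2086 of 12568 tested genes changed at an adjusted p below 0.05 (limma, Benjamini-Hochberg), 1245 higher and 841 lower in Wtap-CKO. Of these, 413 changed by at least 1 on the log2 scale, 284 of them upward and 129 downward. In all 2086 the 3 values of each group lay apart from those of the other, as they did in 37.1% of all tested genes, where chance gives 10%. The submitters state 2348 genes lower and 2764 higher, from a test and thresholds that are not given in the sources used here. The split between higher and lower depended on scaling, and also moved with the filter and the GC and length correction. As deposited, 59.7% of the changed genes were higher. With upper-quartile scaling 45.4% were higher, with each library rescaled to a fixed total (TPM) 33.3%, and with a total that leaves out mitochondrially encoded genes 32.7%. The last 2 scalings shifted the median log2 fold change of all genes by -0.14 and -0.15, so the changes reported here are relative to the median gene. Summed FPKM was 329720 ± 12602 in Wtap-flox and 370382 ± 15939 in Wtap-CKO (SD, n = 3; exact permutation test, two-sided p = 0.1). TPM scaling sets these sums equal, which lowers Wtap-CKO values against those of Wtap-flox. Leaving out Wtap-flox 1, Wtap-flox 2, Wtap-flox 3 or Wtap-CKO 1 lowered the count to 1237, 1189, 1265 and 1189 genes. Those fits have fewer samples, so calls lost in them are not read here as smaller changes. Without Wtap-CKO 3, the library that stood apart, 2016 genes changed and 1643 of them were among the 2086.

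**Figure D1:**
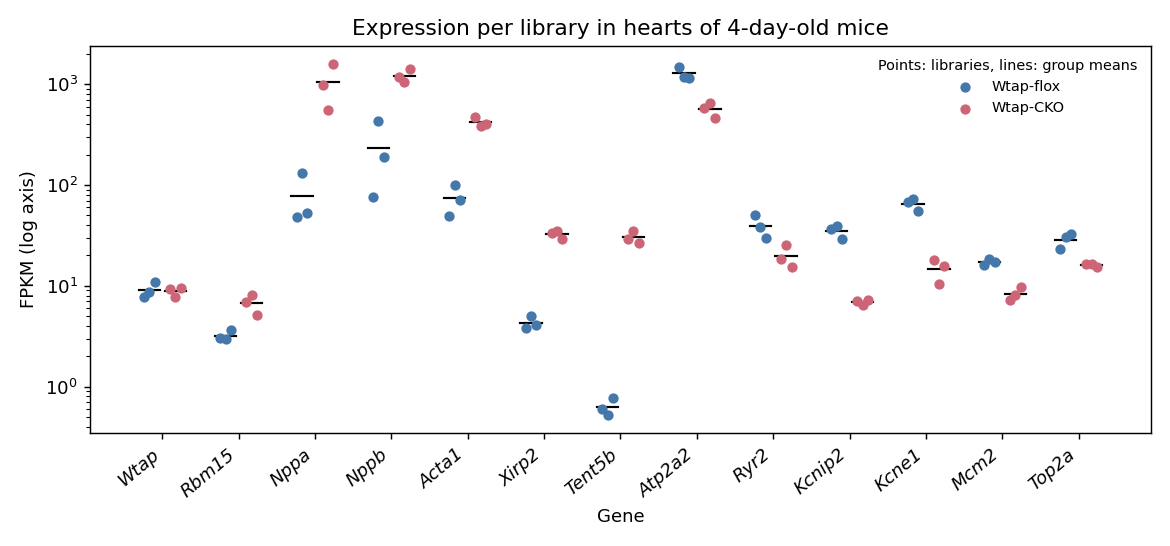
FPKM per library (log axis) of 13 genes in 3 Wtap-flox and 3 Wtap-CKO hearts, with points for libraries and lines for group means. Wtap overlaps between the groups, while Nppa lies between 48.5 and 131 FPKM in Wtap-flox and between 555 and 1606 FPKM in Wtap-CKO.

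On the log2(FPKM + 1) scale the largest rise was that of Tent5b (ENSMUSG00000046694, chromosome 4, 133480132 to 133487938), which encodes a terminal nucleotidyltransferase. It went from 0.630 ± 0.124 to 30.5 ± 4.51 FPKM (SD, n = 3; log2 fold change 4.26, adjusted p = 2.73e-06). The Z-disc gene Myoz1 rose from 1.21 ± 0.336 to 23.5 ± 3.77 FPKM (3.47). The actin-binding regulator Abra (2.54), the matrix gene Adamtsl2 (2.32), the calsequestrin of skeletal muscle Casq1 (1.99), Tuft1 (1.98) and the membrane protein gene Shisa4 (1.91) also rose. Among protein coding genes with a mean of at least 5 FPKM, the largest fall on that scale was that of Kcnip2 (ENSMUSG00000025221, chromosome 19, 45791839 to 45816061), which encodes a subunit of the transient outward potassium current. It went from 35.0 ± 5.53 to 6.92 ± 0.388 FPKM (SD, n = 3; log2 fold change -2.17, adjusted p = 0.000134). Pcp4l1 fell by 1.97, Cabcoco1 fell by 1.95, the dehydrogenase gene Dhrs7c fell by 1.82 and Coq8a, which acts in coenzyme Q synthesis, fell by 1.61. This scale understates the change of genes near the lower limit, such as Tent5b.

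Among genes of the fetal and stress programme of cardiomyocytes, those that changed rose in the libraries labelled Wtap-CKO. Of 18 measured members 11 rose and 0 fell (7 to 12 and 0 over the alternatives), and 13 rose when adjusted over the list alone, with a median log2 fold change of 1.18. Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, rose from 77.4 ± 46.5 to 1051 ± 528 FPKM (SD, n = 3; log2 fold change 3.77, adjusted p = 0.00764). Its neighbour Nppb, for the B-type peptide, rose from 232 ± 181 to 1213 ± 174 FPKM (2.71, adjusted p = 0.0391). Nppb missed the threshold without Wtap-flox 3 or any 1 of the Wtap-CKO libraries, with an adjusted p of up to 0.114. Xirp2, an actin-binding gene of the intercalated disc, rose from 4.32 ± 0.612 to 32.6 ± 3.16 FPKM, and skeletal alpha-actin Acta1 from 73.7 ± 25.6 to 421 ± 44.0 FPKM. The matricellular genes Ctgf (2.33) and Cyr61 (1.79) also belong to the list. Tnni1, the fetal troponin I, had -0.15 and did not pass. As a list they were called higher (adjusted p = 5.2e-09, camera), with adjusted p = 0.337 with an estimated correlation. Without Wtap-flox 3, 8 members rose.

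Among genes of the mature cardiomyocyte and of cardiac conduction, more fell than rose in the libraries labelled Wtap-CKO. Of 24 listed ion channel and conduction genes 19 reached a mean of 1 FPKM over the 6 libraries, and the others were not tested. Of the 19, 7 fell and 0 rose (10 fell and 1 rose, adjusted over the list alone, and 5 to 10 and 0 to 1 over the alternatives), with a median of -0.44. Besides Kcnip2, these included Kcne1 (-2.10), a subunit of the slow delayed rectifier, Kcnj3 (-1.39), a channel opened by acetylcholine, the channel gene Kcnj11 (-1.04), whose product is closed by ATP, and the pacemaker channel gene Hcn2 (-0.72). Hcn4 had 0.53 (adjusted p = 0.0812). Camera called the list lower (adjusted p = 0.00178), with adjusted p = 0.508 with an estimated correlation. Of 19 mature cardiomyocyte genes 8 fell and 2 rose (9 and 2, adjusted over the list alone, and 4 to 10 and 0 to 2 over the alternatives), also with a median of -0.44. Asb15 fell from 3.37 ± 1.59 to 0.235 ± 0.0863 FPKM, the mitochondrial creatine kinase Ckmt2 fell by 1.28 and the glucose transporter Slc2a4 fell by 0.65, while Lrrc10 rose by 0.55. Lrrc10 missed the threshold without any 1 of 5 libraries, at an adjusted p of up to 0.14. This list was called lower as well (adjusted p = 0.00178), with adjusted p = 0.337 with an estimated correlation. Without Wtap-flox 1, Wtap-flox 2 or Wtap-CKO 1, 4 of its members fell, and 5 without Wtap-flox 3, and 0 rose in each of these fits. The median of the mature genes was -0.27 without Wtap-flox 2, -0.26 without Wtap-CKO 2 and -0.67 with quantile normalization, and that of the channel genes was -0.25 without a filter. The mean log2 deviation of the mature genes from their mean over the 6 libraries was 0.02 in Wtap-CKO 3. It was -0.26 in Wtap-CKO 1 and -0.38 in Wtap-CKO 2, against 0.12 to 0.28 in the Wtap-flox libraries.

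Among genes listed for calcium handling some rose and others fell. Of 20 measured members 3 rose and 4 fell (3 and 5, adjusted over the list alone, and 1 to 5 and 2 to 5 over the alternatives), and the list was not called (adjusted p = 0.495, median -0.12). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 1279 ± 188 to 564 ± 92.9 FPKM (SD, n = 3; log2 fold change -1.18, adjusted p = 0.0052). Ryr2, its calcium release channel, fell from 39.7 ± 10.3 to 19.7 ± 5.18 FPKM (-0.97, adjusted p = 0.0233). Ryr2 missed the threshold without Wtap-flox 1, Wtap-flox 2, Wtap-CKO 1 or Wtap-CKO 3, at an adjusted p of up to 0.0804. Triadin, Trdn, fell by 0.70, while the small muscle protein gene Smpx rose by 1.05. Without Wtap-flox 1, Wtap-flox 2, Wtap-flox 3 or Wtap-CKO 1, 1 member rose, and 5 rose without Wtap-CKO 3. Without Wtap-flox 1 or Wtap-CKO 1, 2 fell. Of 29 sarcomere genes 5 rose and 3 fell (6 and 4, adjusted over the list alone, and 4 to 6 and 0 to 4 over the alternatives). Csrp3 (1.11), Myoz2 (0.98) and Pdlim5 (0.83), which encode Z-disc proteins, rose, and Nebl fell by 0.75. Without Wtap-flox 1, Wtap-flox 3 or Wtap-CKO 2, 1 sarcomere gene fell. The sarcomere list was not called (adjusted p = 0.769), and its median of -0.11 lay below 0 while its mean of 0.06 and the direction of the test lay above. The cardiac myosins did not pass, Myh6 having -0.13 (3417 ± 799 against 3055 ± 166 FPKM) and Myh7 having 0.65 (111 ± 40.7 against 175 ± 68.2 FPKM, adjusted p = 0.23).

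Among 20 cardiac transcription factors 2 rose and 1 fell (3 and 1, adjusted over the list alone, and 1 to 5 and 1 to 6 over the alternatives), and the list was not called (adjusted p = 0.636, median -0.03). Hand2 rose by 0.66, and the homeodomain gene Hopx fell by 0.85. Without Wtap-flox 2, Wtap-flox 3, Wtap-CKO 1 or Wtap-CKO 2, 1 member rose, and without Wtap-CKO 2, 5 fell. Mef2a had -0.48 (adjusted p = 0.0734) and Mef2c -0.41 (adjusted p = 0.0834). Neither passed, although no value of Mef2a or Mef2c in Wtap-CKO reached those in Wtap-flox. Tbx5 (0.41), Nkx2-5 (-0.19) and Gata4 (0.06) did not pass, and the sign for Gata4 turned under upper-quartile, quantile and total scaling.

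Among genes of the cell cycle, those that changed fell in the libraries labelled Wtap-CKO. Of 32 G1/S and DNA replication genes 21 fell and 0 rose (26 and 0, adjusted over the list alone, and 10 to 27 and 0 over the alternatives), with a median log2 fold change of -0.67. Mcm2, Mcm4 and Mcm6, subunits of the replicative helicase, fell by 0.98, 0.87 and 0.95. Mcm2 (ENSMUSG00000002870, chromosome 6, 88883474 to 88898780) went from 17.4 ± 1.25 to 8.35 ± 1.21 FPKM (SD, n = 3; adjusted p = 0.0022). The licensing factor Cdt1, whose locus overlaps a predicted gene, fell from 18.9 to 8.87 FPKM. Of 32 G2/M genes 12 fell and 0 rose (18 and 0, adjusted over the list alone, and 4 to 22 and 0 over the alternatives), with a median of -0.47. They included topoisomerase Top2a (-0.78), the mitotic motor Kif11 (-0.82), the checkpoint kinase Bub1b (-0.79) and the spindle protein gene Nusap1 (-0.71). Both lists were called lower (adjusted p = 3.68e-12 and 3.66e-08), with adjusted p = 0.337 and 0.531 with an estimated correlation. By fry the G2/M list was not called (adjusted p = 0.111). With 1 library left out, between 10 (without Wtap-flox 2) and 21 G1/S genes fell. Between 4 (without Wtap-flox 2 or Wtap-flox 3) and 20 (without Wtap-flox 1) G2/M genes fell, and with TPM scaling 21.

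**Figure D2:**
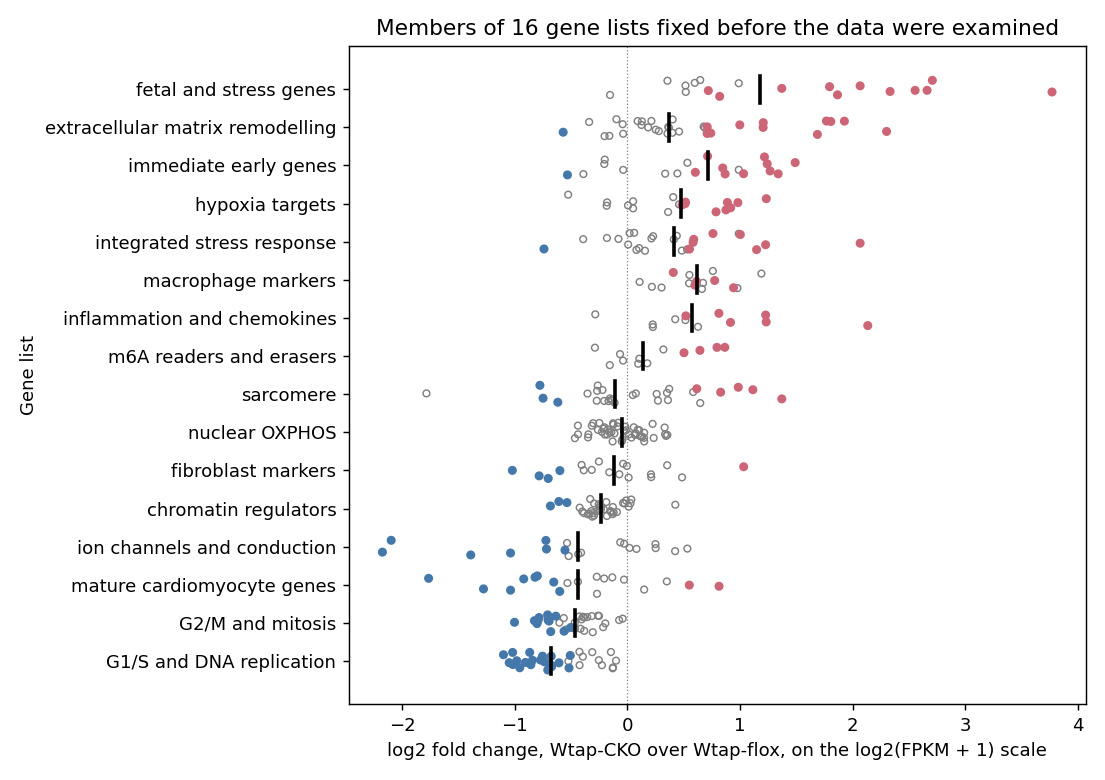
Log2 fold change (Wtap-CKO over Wtap-flox, on the log2(FPKM + 1) scale) of the measured members of 16 gene lists. Each point is a gene, filled points passed at an adjusted p below 0.05, and black lines are list medians. The medians run from 1.18 for fetal and stress genes to -0.67 for G1/S and DNA replication genes.

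In the libraries labelled Wtap-CKO the counts of changed genes of energy metabolism depended on scaling. None of 48 nuclear genes of oxidative phosphorylation passed, over all genes or adjusted over the list alone (0 rose and 0 to 10 fell over the alternatives, adjusted p = 0.193, median -0.05), while 3 were lower at an unadjusted p under 0.05. Sdha of complex II had -0.47 (adjusted p = 0.0536) and Uqcrq of complex III had 0.34. Leaving out Wtap-CKO 3 gave 2 members lower and a median of -0.23, and the list was then called lower (adjusted p = 5.14e-05), as it was without Wtap-flox 1 (adjusted p = 0.0432). Without Wtap-CKO 2 its median was 0.14. With quantile normalization 10 members fell and the list was called lower (adjusted p = 3.85e-05), and 5 fell with TPM scaling. Array weights (adjusted p = 0.0285) and the GC and length correction (adjusted p = 0.00977) also called the list lower. All these calls are by camera at a correlation of 0.01, while the estimated correlation of this list was 0.748. With the estimated correlation camera on all 6 libraries gave adjusted p = 0.827, and fry gave 0.759. None of 13 mitochondrially encoded genes passed on either adjustment (0 rose and 0 to 1 fell over the alternatives, median -0.12), and 1 was lower at an unadjusted p under 0.05, mt-Nd3 at -1.18 (adjusted p = 0.0966). Mitochondrially encoded genes held 23.4 ± 1.51% of the summed FPKM in Wtap-flox and 22.9 ± 0.811% in Wtap-CKO (SD, n = 3; exact permutation test, two-sided p = 0.6). The 20 highest genes of a library held 30.9 ± 0.766% and 31.8 ± 1.55% (exact permutation test, two-sided p = 0.5). Of 28 fatty acid oxidation genes 1 rose and 2 fell (1 and 0, adjusted over the list alone, and 0 to 3 and 0 to 8 over the alternatives; list adjusted p = 0.1). With quantile, TPM or mitochondria-free scaling 8 fell and 0 rose. The list was called lower with quantile normalization (adjusted p = 0.00187), without a filter (adjusted p = 0.0292) and at a mean of at least 5 FPKM (adjusted p = 0.0434). None fell without any 1 of the libraries other than Wtap-CKO 3, and 3 rose without Wtap-flox 1. Acot2 rose by 0.70, and the electron transfer genes Etfa and Etfdh fell by 0.54 and 0.45. With 1 library left out the adjusted p of these 3 reached 0.0683, 0.133 and 0.142, and Etfdh passed in none of these 6 fits. Of 21 glycolysis genes 6 rose and 1 fell (6 and 2, adjusted over the list alone, and 3 to 6 and 1 to 2 over the alternatives; list adjusted p = 0.0898). The lactate exporter Slc16a3 rose from 4.57 ± 2.15 to 18.0 ± 2.95 FPKM, the glucose transporter Slc2a1 rose by 1.23, the phosphofructokinase gene Pfkp rose by 0.83, and Pfkm, which encodes the muscle isoform, fell by 0.86. Without Wtap-flox 1, Wtap-flox 3, Wtap-CKO 2 or Wtap-CKO 3, 3 glycolysis genes rose. With TPM scaling 3 rose and 2 fell. Glycolysis was called higher without Wtap-flox 2 (adjusted p = 0.011), without a filter (adjusted p = 0.0357) and at a mean of at least 0.1 FPKM (adjusted p = 0.0462).

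Among genes of several stress responses, more rose than fell in the libraries labelled Wtap-CKO. Of 25 genes of the integrated stress response 8 rose and 1 fell (11 and 2, adjusted over the list alone, and 5 to 11 and 0 to 2 over the alternatives; median 0.41). Gdf15, a secreted stress cytokine, rose from 2.82 ± 1.32 to 14.7 ± 3.37 FPKM (SD, n = 3; log2 fold change 2.07, adjusted p = 0.00273). Ddit4 (1.23), an inhibitor of mTOR signalling, and the amino acid transporter subunit Slc7a5 (1.15) rose, and Aldh1l2 fell by 0.74, at an adjusted p of up to 0.0933 with 1 library left out. Camera called it higher (adjusted p = 0.00144), with adjusted p = 0.337 with an estimated correlation, and 5 members rose without Wtap-flox 3 or Wtap-CKO 1. Its median was 0.21 without Wtap-flox 1 or without a filter, 0.23 at a mean of at least 0.1 FPKM and 0.25 with the GC and length correction. Of 18 hypoxia targets 9 rose and 0 fell (11 and 1, adjusted over the list alone, and 6 to 12 and 0 to 1 over the alternatives; median 0.47), among them P4ha1 (0.79), Adm (0.92) and carbonic anhydrase Car9 (0.87), while Pfkfb4 had -0.52 (adjusted p = 0.0518). This list was called (adjusted p = 0.0012), with adjusted p = 0.337 with an estimated correlation, and 6 members rose without Wtap-flox 1 or Wtap-CKO 1, and its median was 0.31 with mitochondria-free scaling. Of 19 immediate early genes 10 rose and 1 fell (13 and 2, adjusted over the list alone, and 7 to 11 and 0 to 2 over the alternatives; median 0.71). Fos rose from 1.84 ± 0.685 to 6.85 ± 0.759 FPKM, and Btg2 (1.24), Ier3 (1.22) and Myc (1.03) rose. Jun fell by 0.53, at an adjusted p of up to 0.107 with 1 library left out. The list was called (adjusted p = 0.000386), with adjusted p = 0.469 with an estimated correlation.

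Some genes of cell death and DNA damage changed, with lists that were not called. Of 24 p53 targets 5 rose and 0 fell, also adjusted over the list alone (4 to 11 and 0 to 2 over the alternatives, list adjusted p = 0.0658, median 0.27). They included the cyclin kinase inhibitor Cdkn1a (0.89), Phlda3 (1.07) and the nuclease gene Aen (0.85), while Trp53inp1 had -0.49 (adjusted p = 0.105). The p53 list was called without Wtap-CKO 2 (adjusted p = 0.0267), and also without a filter, at a mean of at least 0.1 FPKM, with TPM or mitochondria-free scaling, with array weights and by fry (adjusted p between 0.0144 and 0.0436). Of 22 genes of apoptosis and necroptosis 8 rose and 1 fell (8 and 3, adjusted over the list alone, and 3 to 8 and 0 to 2 over the alternatives; list adjusted p = 0.109, median 0.11). Those that rose have opposite roles: Bcl2 (0.89) and Bcl2l1 (0.58) protect cells, and Bnip3 (0.98) promotes death and mitophagy. The TWEAK receptor Tnfrsf12a rose by 1.57. It missed the threshold without Wtap-flox 3 or Wtap-CKO 2, at an adjusted p of up to 0.0652. Without Wtap-flox 3, 3 members of this list rose, and 4 without Wtap-flox 1 or Wtap-CKO 1. Its median turned to -0.04 with TPM and -0.05 with mitochondria-free scaling. Apoptosis was called without a filter (adjusted p = 0.0499) and by fry (adjusted p = 0.0409). Of 17 genes of the unfolded protein response 2 rose and 1 fell (4 and 1, adjusted over the list alone, and 0 to 6 and 0 to 2 over the alternatives; list adjusted p = 0.0846, median 0.24). Xbp1 (0.59) and Manf (0.65) rose and Herpud1 fell by 0.50. Without Wtap-flox 1, Wtap-flox 2, Wtap-flox 3 or Wtap-CKO 1, 0 members passed in either direction, and the list was called without Wtap-CKO 2 (adjusted p = 0.0375), without a filter, at a mean of at least 0.1 FPKM and with array weights (adjusted p between 0.0144 and 0.0448).

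Of 33 extracellular matrix genes 11 rose and 1 fell in the libraries labelled Wtap-CKO (13 and 1, adjusted over the list alone, and 9 to 15 and 0 to 2 over the alternatives; median 0.37). The growth factor gene Tgfb2 rose from 5.49 ± 0.503 to 23.8 ± 3.61 FPKM (SD, n = 3; log2 fold change 1.93, adjusted p = 0.000204). Its relative Tgfb3 (1.21) and the thrombospondin gene Thbs1 (1.69) rose, while Thbs2 fell by 0.57, at an adjusted p of up to 0.0625 with 1 library left out. Camera called these genes higher (adjusted p = 2.14e-05), with adjusted p = 0.508 with an estimated correlation, and their median was 0.24 with quantile, 0.20 with TPM and 0.19 with mitochondria-free scaling. Of 18 fibroblast markers 1 rose and 4 fell (2 and 5, adjusted over the list alone, and 1 to 4 and 2 to 6 over the alternatives; list adjusted p = 0.215, median -0.12). The collagen-binding proteoglycan genes Lum (adjusted p = 0.00468) and Dcn fell, Dcn from 50.9 to 33.4 FPKM, Islr fell by 0.70, and the transcription factor Meox1 rose by 1.03. Dcn missed the threshold without any 1 of 5 libraries, at an adjusted p of up to 0.124, and 2 markers fell without any library but Wtap-CKO 3.

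Among markers of vascular cells some rose and others fell. Of 18 endothelial markers 2 rose and 2 fell (3 and 2, adjusted over the list alone, and 2 to 5 and 0 to 3 over the alternatives; list adjusted p = 0.495, median 0.14). Without Wtap-CKO 2, 4 rose. The junction protein gene Cldn5 rose from 59.1 ± 6.89 to 120 ± 7.51 FPKM and Emcn rose by 0.87. The apelin receptor Aplnr fell by 0.97, and the growth factor receptor Kdr fell by 0.43, with an adjusted p of 0.0497 that lay above the threshold without any 1 of the 6 libraries and reached 0.161. Of 10 endocardial and lymphatic markers 3 rose and 0 fell, also adjusted over the list alone (1 to 3 and 0 to 1 over the alternatives, list adjusted p = 0.114, 0.0191 by fry, median 0.30), namely Plvap (0.96), Vwf (0.65) and Lyve1 (0.60). Prox1 had -0.48 and did not pass. Only 1 of them rose without Wtap-flox 3 or Wtap-CKO 1. Of 14 smooth muscle and pericyte markers 2 rose and 2 fell (2 and 3, adjusted over the list alone, and 0 to 2 and 1 to 4 over the alternatives; list adjusted p = 0.7, median -0.03). Cnn1 (1.11) and Cspg4 (0.67) rose, and Abcc9 fell by 1.13 and Vtn fell from 2.97 to 0.905 FPKM. With 1 library left out the adjusted p reached 0.0533 for Cnn1, 0.0916 for Cspg4 and 0.0968 for Vtn, and neither Cnn1 nor Cspg4 passed without Wtap-flox 3 or Wtap-CKO 1. Of 6 epicardial markers 1 rose and 0 fell (3 and 0, adjusted over the list alone, and 1 to 3 and 0 over the alternatives; median 0.81), which was the keratin gene Krt19 (1.35), and Tbx18 had 0.85 (adjusted p = 0.0618). That list was called higher (adjusted p = 0.00826), with adjusted p = 0.337 with an estimated correlation, and its median was 0.15 without a filter and 0.28 at a mean of at least 0.1 FPKM. Without Wtap-CKO 2, 3 epicardial markers rose, and 2 without Wtap-CKO 3.

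Among markers of immune cells and genes of inflammation, those that changed rose in the libraries labelled Wtap-CKO. Of 15 macrophage markers 5 rose and 0 fell (9 and 0, adjusted over the list alone, and 0 to 9 and 0 over the alternatives; median 0.61). The complement genes C1qb and C1qa rose from 9.51 ± 0.922 to 19.8 ± 6.38 and from 10.5 ± 1.04 to 19.3 ± 5.80 FPKM (SD, n = 3), and the endotoxin co-receptor Cd14 rose by 0.61. With 1 library left out the adjusted p reached 0.0563, 0.109 and 0.0865 for these 3. The mean log2 deviation of the macrophage markers was 0.69 in Wtap-CKO 3, 0.15 in Wtap-CKO 1 and 0.10 in Wtap-CKO 2. The list was called (adjusted p = 0.000127), with adjusted p = 0.337 with an estimated correlation, and its median was 0.41 without Wtap-CKO 3. Of its members 0 passed without Wtap-flox 2, 1 without Wtap-flox 1 and 2 without Wtap-flox 3 or Wtap-CKO 1, with medians of 0.62, 0.66, 0.65 and 0.72 in these fits. Of 6 monocyte and neutrophil markers 1 rose and 0 fell, also adjusted over the list alone (0 to 2 and 0 over the alternatives, list adjusted p = 0.0645, median 0.99). It was Retnlg, at 0.369 ± 0.171 against 3.59 ± 1.87 FPKM, while S100a8 had 1.71 with an SE of 0.76. Their mean deviation was 1.70 in Wtap-CKO 3, against -0.03 in Wtap-CKO 1 and -0.15 in Wtap-CKO 2. The list was called without Wtap-CKO 1 (adjusted p = 0.00922) or Wtap-CKO 2 (adjusted p = 0.012), and in 6 further settings of filter or scaling (adjusted p between 0.002 and 0.0242). With an estimated correlation, which was 0.935 for this list, camera on all 6 libraries gave adjusted p = 0.613, and fry gave 0.242. Of 12 genes of inflammation and chemokines 6 rose and 0 fell (8 and 0, adjusted over the list alone, and 0 to 8 and 0 over the alternatives; median 0.57). Ccl2, a monocyte attractant, rose from 0.981 ± 0.217 to 8.40 ± 4.91 FPKM, and Ccl7 (1.23), the oncostatin M receptor Osmr (0.92) and Socs3 (0.81, adjusted p of up to 0.0567 with 1 library left out) rose. Of 16 interferon response genes 3 rose and 0 fell, also adjusted over the list alone (0 to 5 and 0 over the alternatives, median 0.25), namely Ifit3 (0.56), Oasl2 (0.56) and Rtp4 (0.49). None of the interferon genes passed without Wtap-flox 1, Wtap-flox 3 or Wtap-CKO 1, and the list median lay between 0.20 and 0.31 with 1 library left out. The lists of inflammation and interferon genes were called (adjusted p = 0.000387 and 0.00652), with adjusted p = 0.337 for both with an estimated correlation. The 2 lists and that of epicardial markers were no longer called at a mean FPKM of at least 5 (adjusted p = 0.87, 0.127 and 0.0855), where each held 3 tested genes. At that mean the medians were 0.23, 0.59 and 0.85 in this order. The interferon median was 0.13 with TPM, 0.12 with mitochondria-free scaling and 0.37 with limma-voom.

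Of 36 chromatin regulators 3 fell and 0 rose in the libraries labelled Wtap-CKO (2 and 0, adjusted over the list alone, and 2 to 11 and 0 over the alternatives; median -0.24), namely the methyltransferase gene Ezh2 (-0.68), Smarcd1 (-0.61) and Hdac9 (-0.54), while Dot1l had 0.43. Hdac9 missed the threshold without any 1 of 5 libraries, at an adjusted p of up to 0.11. With TPM scaling 11 fell (median -0.38), 9 with mitochondria-free scaling (median -0.39) and 7 with upper-quartile scaling, quantile normalization or the GC and length correction. The list was called lower (adjusted p = 0.000386), with adjusted p = 0.337 with an estimated correlation. Of 36 splicing factors 1 rose and 1 fell, also adjusted over the list alone (0 to 1 and 0 to 3 over the alternatives, list adjusted p = 0.0977, median -0.11). Rbfox1 fell by 1.22, and Ptbp2 rose by 0.45. Upper-quartile, quantile and total scaling called the list lower (adjusted p between 0.0022 and 0.0469). The adjusted p of Ptbp2 reached 0.0974 with 1 library left out. None of 46 cytosolic ribosomal protein genes passed on either adjustment (0 to 1 rose and 0 fell over the alternatives) and 5 were higher at an unadjusted p under 0.05, although their median was 0.42 and the list was called higher (adjusted p = 0.0001), with adjusted p = 0.639 with an estimated correlation and 0.264 by fry. Rplp1 had 976 ± 158 against 1460 ± 416 FPKM. The mean deviation of the ribosomal list was 0.75 in Wtap-CKO 3, 0.09 in Wtap-CKO 1 and -0.20 in Wtap-CKO 2, and its median was 0.18 without Wtap-CKO 3, 0.20 with quantile, 0.24 with mitochondria-free and 0.25 with TPM scaling.

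The remaining lists held few measured genes or no changes. None of 7 erythroid markers (list adjusted p = 0.453), 3 adipocyte markers (0.769), 4 sex-linked genes (0.453) or 14 imprinted growth genes (0.576) passed, over all genes or adjusted over the list alone. Over the alternatives up to 1 adipocyte marker rose, and up to 2 imprinted genes rose and 1 fell. At an unadjusted p under 0.05 were 1 adipocyte marker (higher) and, of the imprinted genes, 2 higher and 1 lower. Hba-a2 had 0.91 with an SE of 0.59, Cidea and Adipor2 had 0.45 and -0.24, the Y-linked Kdm5d had -0.27, and Plagl1 and Mest had 0.49 (adjusted p = 0.0512) and -0.52 (adjusted p = 0.0704). No lymphocyte or thymus marker reached a mean of 1 FPKM. Of skeletal muscle, neural crest, and lung and liver markers 1 each was measured and no list test was made. Myl1 fell by 0.93. Ager had 0.50 and passed when adjusted over the list alone, a list of 1 gene. None of 24 transcription factor families named in the file, with 762 tested genes, was called by camera, and 3 of them had an unadjusted p under 0.05.

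Over the 37 lists tested, camera called 10 higher and 5 lower, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. By fry, which tests a list's own genes without comparing them with others, 17 were called. These held 13 of the 15 called by camera, all but the G2/M and ribosomal lists, and 4 others. Camera with its preset correlation also called between 7 and 14 lists when the 6 libraries were divided into mixed groups of 3. No mixed division gave any changed gene. Every mixed group holds libraries of both labels. The difference between the labels then adds to the spread within groups, and part of it stays between them. Neither count is therefore a value for no difference, and they do not rank the counts of single genes above the list tests. The median of each of the 22 lists that were not called moved by over 1.5 times in at least 1 setting. Where such a median lies near 0, a small shift is enough. Medians of called lists moved as far too, such as those of the integrated stress response and the ribosomal list, so such moves do not set the lists apart.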

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

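Limma-voom on recovered reads and the correction for GC content and gene length were chosen after the results were seen. None of the 2086 changed genes had the opposite sign in any setting that tested it. Their groups did not overlap, so leaving out a library or another pseudocount, filter or variance model could not turn a sign. Upper-quartile, quantile, TPM and mitochondria-free scaling and the GC and length correction could have done so. The 115 genes named as changed gave 2392 values under alternatives other than median-ratio scaling, which is that of the deposited values. Of these 2180 passed in the same direction, 212 did not pass and 0 had the opposite sign, and 84 of the 115 passed with any 1 library left out. Many of the 115 were named for a small adjusted p or a large change in these data, which favours their passing again. Over all changed genes, 1128 of 2072 passed again without Wtap-CKO 1, 1137 of 2069 without Wtap-flox 2 and 1643 of 2070 without Wtap-CKO 3. Without a filter 1053 of 2086 passed again, and at a mean of at least 5 FPKM 1333 of 1333. Without a filter 1206 genes changed, 723 higher and 483 lower, among 27201 tested, and at a mean of at least 5 FPKM 992 were higher and 471 lower. Scaling moved the balance, with 774 higher and 1590 lower without mitochondrially encoded genes, and 799 and 1600 for TPM. Array weights gave 3732 changed genes, 2056 higher and 1676 lower, and the GC and length correction gave 1396 higher and 1325 lower. A log2 fold change of at least 1 left 413 changed genes, 284 changed genes higher in Wtap-CKO and 129 changed genes lower in Wtap-CKO, and an adjusted p under 0.01 left 785, 514 and 271. With 1 library left out, between 1189 (without Wtap-flox 2 or Wtap-CKO 1) and 2016 (without Wtap-CKO 3) genes changed, 715 to 1187 of them higher and 417 to 829 lower. Those fits have fewer samples. The shift with TPM scaling follows from the higher summed FPKM in Wtap-CKO. Why these sums differed, and the cause of the other shifts, were not tested.

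A replicate block gave 1673 changed genes, 1569 of them among the 2086. Deviations of libraries with the same number correlated at -0.22, -0.08 and -0.08, so the numbers gave no sign of pairing the hearts. Libraries with different numbers correlated at -0.14 (Wtap-flox 3 with Wtap-CKO 2) to 0.26 (Wtap-flox 3 with Wtap-CKO 1). A pairing under other numbers was not tested. With the block 15 of the 115 named genes did not pass, among them Nppa, Nppb and all 3 interferon genes, and the monocyte and neutrophil list was called (adjusted p = 0.039).

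Of 15 lists called, 0 were called with an estimated correlation. Without a filter the lists of m6A readers and erasers, fatty acid oxidation, glycolysis, the unfolded protein response, p53 targets, apoptosis, and monocytes and neutrophils were called too (adjusted p between 0.002 and 0.0499). Wtap had 0.01 with array weights (0.00758) and with the GC and length correction (0.00738), and between -0.13 and 0.0863 with 1 library left out. Gata4 had -0.0294 with upper-quartile, -0.17 with quantile, -0.12 without mitochondrially encoded genes, -0.11 with TPM, -0.0526 with array weights, -0.0357 with the GC and length correction and -0.0218 to 0.19 with 1 library left out. For some lists that were not called, the direction of the camera test turned, not always with the sign of the median. Their medians in those settings were as follows. The mitochondrially encoded median was -0.12 without a filter, 0.11 with array weights and -0.11 with the GC and length correction. That of the sarcomere list was -0.11 at 5 FPKM, -0.16 with quantile normalization, -0.0396 with array weights and -0.0802 with the GC and length correction. Array weights gave -0.0122 for erythroid and -0.18 for adipocyte markers, and the GC and length correction gave 0.0729 for sex-linked genes. With 1 library left out, medians ran from -0.19 to 0.10 for cardiac transcription factors, -0.0941 to -0.00675 for sarcomere, -0.23 to 0.14 for nuclear OXPHOS, -0.24 to 0.10 for mitochondrially encoded genes, -0.11 to 0.57 for erythroid and -0.0434 to 0.36 for adipocyte markers. The share of mitochondrially encoded genes differed by 0.321 percentage points over reads and that of the 20 highest genes by -0.0926. The cause of these was not tested. For a gene of 1 kb the depth set a step of 0.0564 to 0.0647 FPKM per read.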

Other observations

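Chosen after the results were seen were the tests of the splits for changed genes, of closeness to the own group, of the Wtap interval, of the exon-number slope, of the FPKM of receptor genes and of macrophage markers without Wtap-CKO 3.

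Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, itself, with 2086 against a highest other of 0. For lists called by camera 1 split gave as many, the real one, with 15 against a highest other of 14. The 10 splits are too few for a share under 0.05. In the other splits both groups hold libraries of both labels, so their counts are not values for no difference.

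Wtap was not lower in the libraries labelled Wtap-CKO. All 6 libraries were closer to their own group, which argues against an exchange of some libraries between the groups. An exchange of the whole groups would leave this closeness unaltered. It would turn a fall of Wtap into a rise, and the 95% interval allowed a ratio of at most 1.23 on the FPKM + 1 scale. An exchange of the whole groups therefore does not account for the flat Wtap value, and that value does not tell whether the labels are exchanged. Reads from outside the deleted part, or from cells that kept the gene, may hold the whole-gene value up, and this stays open because the largest fall inside the 95% interval was 22.4% of FPKM + 1 (24.8% of FPKM) and the deleted exons are not stated. An effect of the deletion on Wtap transcripts is a biological alternative that was not tested.

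Of 2154 genes with 2 to 4 exons 401 rose and 101 fell in the libraries labelled Wtap-CKO (median 0.15), against 63 and 141 of 1692 with at least 20 (median -0.12). Without covariates the slopes on exon number overlapped between the groups (gap -0.00274, larger SD 0.0470, exact permutation test, two-sided p = 0.2). With log2 length, GC and level in the fit as linear terms they lay apart by 0.0473 (larger SD 0.0101, exact permutation test, two-sided p = 0.1). This argues against a linear length or GC bias as the whole cause. A bias of another shape was not tested by this fit. Reads of olfactory, vomeronasal and trace amine receptor genes were 1.30 times as many per library size in Wtap-CKO, the direction that genomic DNA predicts. Their pooled FPKM was at most 0.00816 in any library, against the 0.918 FPKM that the rise would need, which argues against genomic DNA. The slope on the longest exon had a gap of -0.0180 (larger SD 0.0356), so more reads from long exons stays open. An effect of WTAP on the processing of transcripts by exon number is a hypothesis that was not tested.

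The list of macrophage markers was called higher in the libraries labelled Wtap-CKO (adjusted p = 0.000127, and 0.337 with an estimated correlation), with 5 of 15 past the threshold. A lower share of cardiomyocytes as the only difference would raise fibroblast markers alike. The macrophage minus fibroblast means lay apart by 0.406 (larger SD 0.381; exact permutation test, two-sided p = 0.1), which argues against that. Fibroblast markers themselves changed, 1 up and 4 down, so a lower share together with other changes stays open. Wtap-CKO 3 alone does not account for the higher macrophage markers, since the other Wtap-CKO libraries lay 0.363 above Wtap-flox (larger SD 0.0382). More macrophages, or more of these transcripts per macrophage, may lie behind the difference, and neither was tested.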
